A study of Morus alba with 35 samples.

How the data were processed

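RNA sequencing was analysed for 34 libraries of Morus alba cell suspensions, 12 from control flasks and 22 from elicited flasks, at 0.5, 6, 12, 24, 48 and 72 h. Per the labels' protocols, a suspension 14 days old was filtered, washed and placed in fresh medium, with 32 g of medium per 8 g of cells in each flask, at 25 °C in the dark. Elicited flasks received 50 mM methylated cyclodextrin and 100 µM methyl jasmonate, and controls the same volume of ethanol (2.1 µL per mL). Each replicate was a separate flask per the labels, and nothing states whether the flasks came from separate parent suspensions, so p-values measure the spread between flasks. RNA with an integrity number of at least 7 was used with a stranded mRNA library kit, per the labels. A pooled long-read sample of 4 elicited samples is not analysed here.

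The deposited values were whole-number read counts per gene, with no normalization, in 1 table of 31401 genes with their exon coordinates, and every library's column was matched to its sample by the label in its description. Per the submitters' processing notes the tools were fastp, STAR and featureCounts. Their versions and settings, the genome build, the annotation, whether reads were counted by strand and how reads that map to several genes were treated are not given in the sources used here. Coordinates are those of the deposited table, counted from 1. The table's identifiers carry no gene names or products, and no annotation was used here, so tests of gene lists planned before the data were examined were not run and genes are given by identifier. Of the annotated genes, 2390 share exon bases with another gene (2019 of those tested, 10%). In 25 pairs in which a gene lies on the opposite strand with at least 90% of its bases within its partner, at a mean count of at least 50, the median ratio of the partners' counts was 0.975 and their median correlation over libraries 0.999. Reads were therefore counted for both partners, and sense and antisense genes of such pairs cannot be separated. None of the named genes, and no gene of the runs of 5 or more, shares exon bases with another gene.

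Library totals lay between 17191217 and 18897243 counts, and 3 counts over a control group corresponded to between 0.0698 and 0.0921 CPM. Wilson intervals of 95% are given for shares of genes. Intervals and floors cover counting error only. In the 36 pairs of libraries of 1 group, the chi-square per degree of freedom over genes with at least 20 counts in the pair was 2.79 to 94.7, so no 2 libraries differed by as little as sampling noise and each was counted as 1 replicate.

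Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and 1 quasi-likelihood model (glmQLFit, glmQLFTest) with a mean for each of the 12 groups was fitted to all 34 libraries. Contrasts were elicited minus control at each time, the mean of these 6 differences, F tests of their equality and of time within controls and within elicited cells, and differences from 0.5 h within each treatment. The elicited minus control differences of consecutive times were also contrasted. P-values were adjusted by Benjamini-Hochberg within each contrast and called below 0.05. Log2 CPM for components and levels used a prior count of 2. Standard errors were derived from the test, as the absolute log2 fold change over the square root of the F statistic, and are approximate for very large folds. The design, tests, alternatives and the rule for named genes were fixed before the data were examined, except where stated. Under that rule, in the absence of gene names, the first 2 increases and first 2 decreases by average log2 fold change were named among genes with an adjusted p below 0.05, a mean log2 CPM of at least 2 and the same sign at all 6 times; 2077 and 1644 genes qualified. Overlaps of calls are given beside the number that independent lists of the same sizes would share. Fold changes against a group without reads are bounds computed with 3 counts over that group. Average fold changes come from the fit; those with such a floor in place, for groups without reads or with fewer than 3 counts, were computed after the values were seen, and the naming rule uses the fitted ones.

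The test was checked on simulated counts for 20107 genes with 200 genes changed. For 0.5 h it recovered 63% of the 2-fold and 95% of the 4-fold changes and called 10 unchanged genes, and for 48 h it recovered 67% and 94% and called 2 unchanged genes. With DESeq2 1.42.0 these were 72%, 95% and 12 for 0.5 h, and 71%, 95% and 14 for 48 h. Simulated counts were drawn independently for each gene and library, with no deviation shared by the genes of a library. The changed genes were taken only from those above a minimum mean level. In the real data 51.5% of the tested genes were called at 48 h. Recovery and false calls therefore describe the simulated setting and need not carry over to these libraries.

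Alternatives were DESeq2 size factors, library size alone, the DESeq2 test, no filter beyond 1 count in some library, a change of at least 2-fold, the replicate number of the title or of the description as a block, only the libraries of 1 time, and each library left out in turn, where a group left with 1 library was assumed to vary like the others. Added after the data were seen were the removal of genes that share exon bases (GenomicRanges 1.54.1), the removal of elicited 12 h replicate 4 and elicited 48 h replicate 3, and 3 elicited libraries at every time. Neighbouring genes were tested against 10000 shuffles of calls among genes, and exon numbers against 10000 random lists matched on expression or on expression and length.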

Results

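White mulberry (Morus alba) cell suspensions derived from stem tissue were measured by RNA sequencing after elicitation with methyl jasmonate, a plant defence hormone, together with methylated beta-cyclodextrin, a cyclic sugar used to elicit stilbenes from cultured plant cells. The elicited flasks received 50 mM cyclodextrin and 100 µM methyl jasmonate, and the control flasks received the ethanol carrier alone. Cells were collected at 0.5, 6, 12, 24, 48 and 72 h. Controls had 2 libraries at each time, 12 in all, and elicited cells had 3 libraries at 0.5 and 6 h and 4 at each later time, 22 in all. The 34 libraries held 17191217 to 18897243 counts each over 31401 annotated genes, of which 27266 had a count and 20107 passed the filter on low counts and were tested. The study concerns oxyresveratrol, a stilbene of mulberry, and its design asks how the effect of elicitation changes with time.

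Time in culture moved control and elicited cells along different courses. The first principal component of the tested genes held 41.2% of the variance and the second 25.3%. Control libraries went from a mean of -86.6 on the first component at 0.5 h to 139 at 72 h, while elicited libraries went from -105 to 46.9. On the second component the controls began at -72.2 and ended at -86.7, whereas elicited cells went from -69.1 at 0.5 h to 73.5 at 48 h and 58.2 at 72 h. Correlations of log2 CPM between libraries of 1 group, computed across genes, lay between 0.969 and 0.993, and 30 of the 34 libraries were nearest to the mean of their own group. Elicited 48 h replicate 3 was nearest to the elicited 24 h group, elicited 0.5 h replicate 1 to the 0.5 h controls, control 48 h replicate 1 to the 72 h controls, and control 48 h replicate 2 to the 24 h controls.

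**Figure D1:**
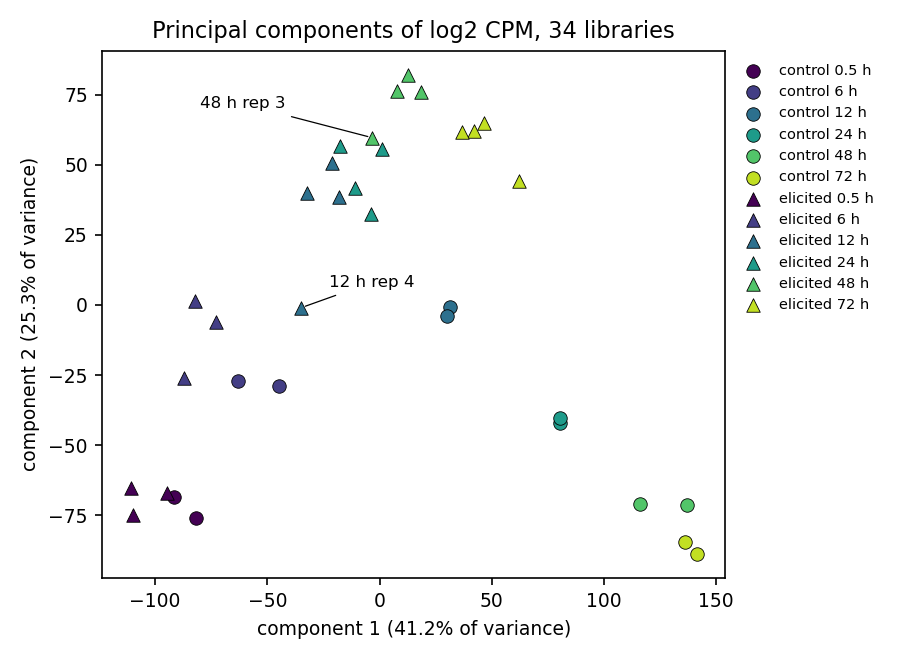
Principal components of log2 CPM of the 20107 tested genes, with 1 point per library (circles, controls; triangles, elicited cells; colour, time). Controls and elicited cells lie close together at 0.5 h and part along both axes from 12 h onward, and elicited 12 h replicate 4 and elicited 48 h replicate 3 lie toward the group of the preceding time.

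Averaged over the 6 times with equal weight, elicited cells had higher transcript levels of 6218 genes and lower levels of 6040. The changes of at least 2-fold were mostly increases, 1665 genes against 993. Among genes that kept the same sign at all 6 times and passed the expression minimum, the greatest fitted average increases were those of Mal_HE_154X_1_chr006g001710, a single-exon gene of 1655 bases on chromosome 6 (1671777 to 1673431, minus strand), and Mal_HE_154X_1_chr004g022320, a single-exon gene of 471 bases on chromosome 4 (21664651 to 21665121, plus strand), with log2 fold changes of 9.05 and 8.59. The controls of these genes held no read at 3 and 2 of the times, so the fitted averages are not exact. With a floor of 3 counts over the control group in place of the fitted fold at those times, the averages were 7.37 and 7.47, and with the floor wherever the control group held fewer than 3 counts they were 7.30 and 7.27. They were the 2 greatest each time, but their order is not settled. The decreases were led by Mal_HE_154X_1_chr012g011270, with 7 exons on chromosome 12 (12330691 to 12333232, minus strand), at -4.05 (SE 0.35), and Mal_HE_154X_1_chr010g002150, with 3 exons on chromosome 10 (1409458 to 1412181, plus strand), at -3.53 (SE 0.18). Their adjusted p-values were 4.61e-15, 1.63e-17, 9.95e-11 and 1.9e-15 in this order (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 20107 genes). The deposited table pairs no gene identifier with a name or product, so what these 4 genes encode is not stated here. With scaling by library size alone the median log2 fold change of all genes lay between -0.08 and -0.24 at the single times and at -0.17 on average, where TMM scaling gave medians between -0.01 and 0.04. The average split then became 4116 higher and 9512 lower, in place of 6218 and 6040, so directions of whole groups of genes hold relative to the median gene.

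The 2 genes with the greatest fitted average increases were separated from controls at every time. Mal_HE_154X_1_chr006g001710 stood at 15.7 ± 8.48 CPM (SD, n = 3) in elicited cells at 0.5 h against 0.368 ± 0.26 CPM (SD, n = 2) in controls. At 48 h it stood at 23.6 ± 9.27 CPM (SD, n = 4), while neither control library held a read, which makes it at least 338-fold higher against a floor of 3 counts over the control group. For this gene the effect was not shown to differ between times (adjusted p = 0.144, edgeR quasi-likelihood F test, Benjamini-Hochberg). Mal_HE_154X_1_chr004g022320 rose from 10.9 ± 1.75 CPM (SD, n = 3) at 0.5 h to 160 ± 56.7 CPM (SD, n = 4) at 48 h in elicited cells, and fell from 2.89 ± 0.527 CPM (SD, n = 2) to no read at 48 h in controls. It was at least 2292-fold higher at 48 h and at least 653-fold higher at 72 h against the same floor, and its effect differed between times (adjusted p = 7.82e-08, same test).

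The 2 genes that led the decreases rose in controls and stayed low in elicited cells. Mal_HE_154X_1_chr010g002150 went from 74.1 ± 4.24 CPM at 0.5 h to 5020 ± 703 CPM at 72 h in controls (SD, n = 2 each), and stood at 59.7 ± 12.7 CPM (SD, n = 3) and 47.1 ± 16.8 CPM (SD, n = 4) at those times in elicited cells. Its log2 fold change was -0.31 at 0.5 h (adjusted p = 0.721) and -6.73 at 72 h (adjusted p = 4.07e-12, edgeR quasi-likelihood, Benjamini-Hochberg). Mal_HE_154X_1_chr012g011270 reached 456 ± 92 CPM (SD, n = 2) in 72 h controls and 0.297 ± 0.139 CPM (SD, n = 4) in elicited cells of that time, a log2 fold change of -10.55 (adjusted p = 1.6e-15), against -0.19 at 0.5 h (adjusted p = 0.925, same test). In both genes the effect differed between times, with adjusted p-values of 4.96e-09 and 7.83e-11 in the order named (edgeR quasi-likelihood F test).

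**Figure D2:**
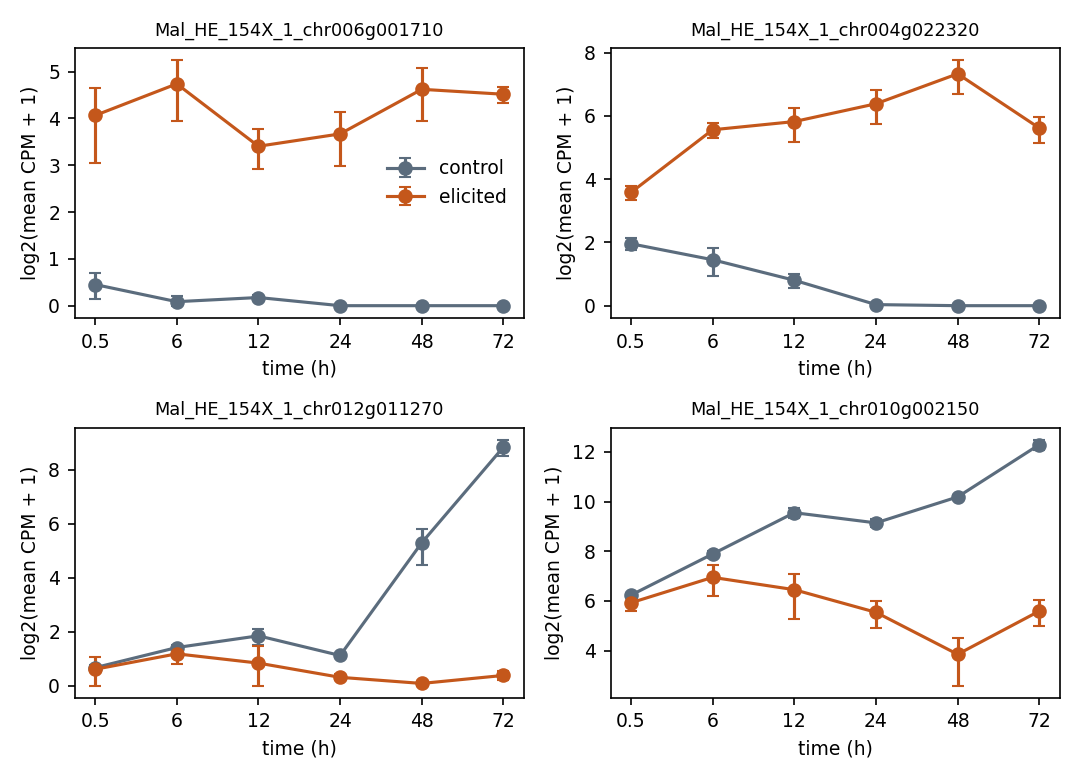
Levels of the 4 named genes over time as log2(mean CPM + 1), controls in grey and elicited cells in orange; bars run from the mean minus 1 SD to the mean plus 1 SD of the CPM on that scale (controls n = 2; elicited n = 3 at 0.5 and 6 h and 4 later). The upper 2 genes are higher in elicited cells at each time, and the lower 2 part from the controls mainly as the control level climbs.

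At 0.5 h, 470 genes were higher in elicited cells and 329 lower. Of these, 184 were at least 2-fold higher and 77 at least 2-fold lower. The median log2 fold change of the 470 genes was 0.79 at 0.5 h, on the data by which they were chosen, and 0.25 at 6 h and 0.39 at 72 h. The 329 lower genes went from a median of -0.67 to -0.14 at 6 h and -0.02 at 72 h. Tested directly, a smaller effect at 6 h than at 0.5 h was called for 23 of the 470 higher genes and 33 of the 329 lower genes (edgeR quasi-likelihood, adjusted p below 0.05). The 23 became 120 without elicited 0.5 h replicate 1 and 4 without elicited 0.5 h replicate 3. Falling medians of genes chosen at 0.5 h therefore do not by themselves show a transient response. Genes with a single exon made up 23.4% of the higher genes (110 of 470; Wilson 95% interval 19.8 to 27.4%), 9.73% of the lower genes (6.97 to 13.4%) and 15.7% of the genes not called; the higher genes were also short, with a median summed exon length of 1028 bases against 2768 bases for the lower genes. The count of 799 changed genes (edgeR quasi-likelihood, Benjamini-Hochberg) rested on single libraries: it was 41 without control replicate 1, 132 without control replicate 2, 136 without elicited replicate 3 and 3010 without elicited replicate 1, the library nearest to the controls, and it was 63 with only the libraries of this time in the fit and 1517 with DESeq2. Scaling by library size alone gave 253 higher and 895 lower.

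At 6 h, 732 genes were higher in elicited cells and 522 lower, and 434 of the former against 98 of the latter changed by at least 2-fold. The median log2 fold change was 1.18 among the higher genes and -0.61 among the lower ones. Single-exon genes were again frequent among the higher genes, at 22.3% (19.4 to 25.4%), against 10.5% (8.18 to 13.5%) of the lower genes. The total of 1254 (edgeR quasi-likelihood, Benjamini-Hochberg) was 635 without control replicate 1, 376 without control replicate 2, 606 without elicited replicate 1 and 493 with only the libraries of this time. Scaling by library size alone gave 619 higher and 685 lower.

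At 12 h the changed genes numbered 4622, with 2577 higher in elicited cells and 2045 lower, and 1099 and 474 of them passed 2-fold. The median log2 fold change was 0.85 for the higher genes and -0.65 for the lower ones. Elicited 12 h replicate 4 stood apart within its group at this time, at -0.964 on the second principal component where the other 12 h elicited libraries lay between 38.4 and 50.7. Without control replicate 1 the count was 2192 and without control replicate 2 it was 1783 (edgeR quasi-likelihood, Benjamini-Hochberg). Scaling by library size alone gave 1573 higher and 4671 lower.

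From 24 h onward the changes were broad and went both ways. The balance of higher and lower calls depends on TMM scaling and holds relative to the median gene. At 24 h, 4366 genes were higher in elicited cells and 3590 lower, with 1919 and 1425 past 2-fold. At 48 h these counts were 5319 and 5043, together 51.5% of the tested genes, with 2734 and 2367 past 2-fold. At 72 h they were 4478 and 4382, with 2276 and 2118 past 2-fold. The median absolute log2 fold change of the called genes was 0.84, 0.98 and 0.99 at the 3 times. The total of 7956 at 24 h was 5299 without control replicate 1, the 3590 lower genes at 24 h were 2331 and 2317 without control replicate 1 or 2, and the totals at 48 and 72 h moved by less than 1.5 times when any 1 library of those times was left out (edgeR quasi-likelihood, Benjamini-Hochberg). Scaling by library size alone gave 2799 higher and 6088 lower at 24 h, 3827 and 7293 at 48 h, and 3557 and 5589 at 72 h. With only the libraries of each time in the fit, the totals were 9380 at 24 h, 8385 at 48 h and 10047 at 72 h. The order of these late times thus depends on the fit.

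**Figure D3:**
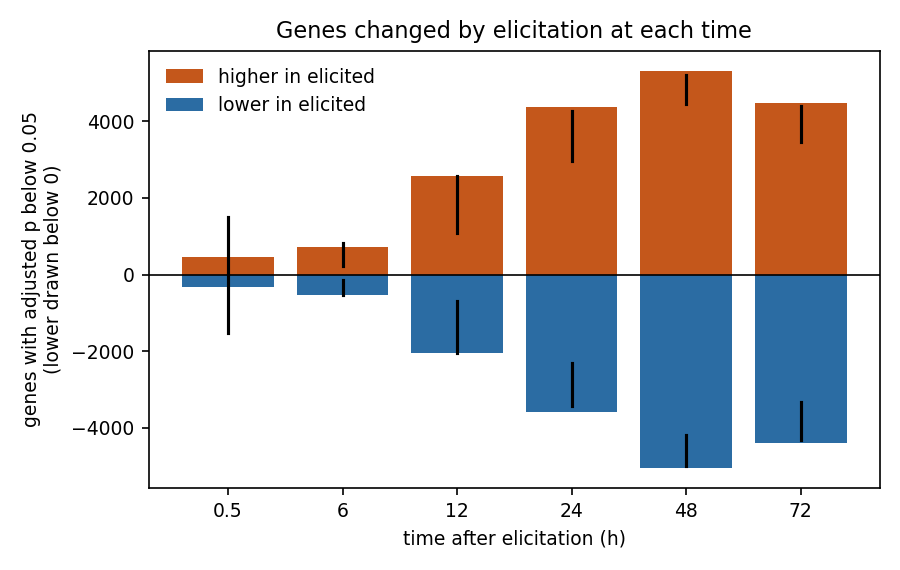
Number of genes higher (orange, above 0) and lower (blue, below 0) in elicited cells at each time, at an adjusted p below 0.05; black lines span the counts obtained when each library of that time is left out in turn. The counts go from 470 and 329 at 0.5 h to 5319 and 5043 at 48 h, and the spans are wide at 0.5 h relative to the bars.

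A set of 51 genes was called higher in elicited cells at all 6 times, and 7 genes were called lower at all 6. The 7 became 20 without elicited 0.5 h replicate 1 and 1 without elicited 0.5 h replicate 3. The median log2 fold change of the 51 genes was 1.55 at 0.5 h, 1.79 at 6 h, 1.89 at 12 h, 2.42 at 24 h, 3.29 at 48 h and 3.13 at 72 h. In elicited cells their median level relative to the 0.5 h controls was 1.45 ± 0.17 log2 units at 0.5 h (SD, n = 3) and 1.63 ± 0.14 at 48 h (SD, n = 4), while in controls it reached -1.29 ± 0.41 at 48 h (SD, n = 2). The number was 14 without control 0.5 h replicate 1, 24 without control 0.5 h replicate 2 and 99 without elicited 0.5 h replicate 1 (edgeR quasi-likelihood at each time). It was 88 with DESeq2, and 89 without elicited 12 h replicate 4 and elicited 48 h replicate 3, an alternative chosen after the data were seen.

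The effect of elicitation depended on the time for 9436 genes, 46.9% of those tested (edgeR quasi-likelihood F test on 5 degrees of freedom, adjusted p below 0.05). Most genes that were called at all were first called between 12 and 48 h. New higher calls numbered 470 at 0.5 h, 631 at 6 h, 1975 at 12 h, 2024 at 24 h, 1324 at 48 h and 525 at 72 h, and new lower calls 329, 493, 1829, 1991, 1704 and 708. A total of 14003 genes were called at 1 or more times. Of these, 812 were higher at 1 time and lower at another, and 809 of the 812 passed the test for dependence on time. The 812 became 1393 without elicited 0.5 h replicate 1.

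Responses of consecutive times correlated more strongly from 12 h onward than before. The log2 fold changes of 2 consecutive times correlated across genes with a Pearson r of 0.258 for 0.5 and 6 h, 0.401 for 6 and 12 h, 0.698 for 12 and 24 h, 0.834 for 24 and 48 h and 0.852 for 48 and 72 h (Spearman 0.246, 0.335, 0.689, 0.786 and 0.774). No library was shared between times, and genes are not independent replicates, so no p-value is attached. Early fold changes were not much larger than their standard errors. Among 6730 genes with a mean log2 CPM of at least 5, the median absolute log2 fold change was 0.21 at 0.5 h and 0.16 at 6 h. The median SE was 0.13 at both times, against 0.42 with an SE of 0.13 at 48 h. Noise can thus lower the early correlations more, and they do not by themselves show an early response of another kind. At 12 h, however, the median absolute log2 fold change of these genes was 0.23 with an SE of 0.13, near the values at 0.5 h. Even so, r over all tested genes was 0.698 for 12 and 24 h but 0.281 for 0.5 and 12 h. Whether noise accounts for the low early correlations is therefore not settled. Among genes higher at 0.5 h, 91 were also higher at 6 h, where 17.1 would be shared by independent lists of these sizes. The corresponding counts were 427 against 93.8 for 6 and 12 h, 2111 against 560 for 12 and 24 h, 3665 against 1155 for 24 and 48 h and 3649 against 1185 for 48 and 72 h. Lower calls were shared by 25 genes against 8.54, 165 against 53.1, 1399 against 365, 2968 against 900.4 and 3242 against 1099 in the same order. Of the higher calls at 24 h, 83.9% were also called at 48 h, and of those at 48 h, 68.6% were also called at 72 h. Calls shared in either direction at 0.5 and 6 h numbered 116, and 20 without control 0.5 h replicate 1, 40 without control 0.5 h replicate 2, 67 without control 6 h replicate 1, 64 without control 6 h replicate 2, 54 without elicited 0.5 h replicate 3 and 298 without elicited 0.5 h replicate 1. The 592 shared at 6 and 12 h became 229 and 260 without control 6 h replicate 1 or 2, 333 and 331 without control 12 h replicate 1 or 2 and 367 without elicited 6 h replicate 1, the 3510 shared at 12 and 24 h became 1862 and 1567 without control 12 h replicate 1 or 2, and the r of 6 and 12 h became 0.24 without control 6 h replicate 1.

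Expression also changed over time within each treatment. In controls 16565 genes (82.4%) changed over the 6 times and in elicited cells 17075 (84.9%), both by edgeR quasi-likelihood F tests. From 0.5 to 72 h, 6337 genes rose and 6698 fell in controls, and 6954 rose and 6886 fell in elicited cells. Much of this course was common to both: 4541 genes rose in both, where independent lists would share 2192, and 4754 fell in both, where they would share 2294. In opposite directions, 570 genes rose in elicited cells and fell in controls, and 348 did the reverse. The changes from 0.5 to 72 h correlated across genes between the treatments with a Pearson r of 0.635 (Spearman 0.654), with no library in common.

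Most genes that differed late had also changed over time in controls. To keep libraries separate, calls at 48 h were set beside the courses from 0.5 to 72 h, and calls at 72 h beside those from 0.5 to 48 h. Of the 5319 genes higher in elicited cells at 48 h, 3491 (65.6%) fell in controls by 72 h, against 1772 for independent lists. Of these 3491 genes, 2105 also fell in elicited cells by 72 h. In elicited cells 1698 of the 5319 (31.9%) rose by 72 h, close to the 1840 of independent lists. The median change to 72 h of these 5319 genes was -0.92 in controls and -0.12 in elicited cells. The 5043 genes lower at 48 h gave the opposite picture, with 3436 (68.1%) rising in controls by 72 h against 1589 for independent lists (2304 of the 3436 also rose in elicited cells), 1311 (26%) falling in elicited cells against 1727, and median changes of 1.01 and 0.34. Of the 4478 genes higher at 72 h, 2837 (63.4%) fell in controls by 48 h against 1494 (1314 of them fell in elicited cells too), and 1867 (41.7%) rose in elicited cells against 1460. Of the 4382 genes lower at 72 h, 2483 (56.7%) rose in controls by 48 h against 1318 (1196 of them rose in elicited cells too), and 1716 (39.2%) fell in elicited cells against 1454. All of these directions are relative to the median gene, and scaling by library size alone gave 5284 of 7293 genes lower at 48 h in place of 3436 of 5043.

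**Figure D4:**
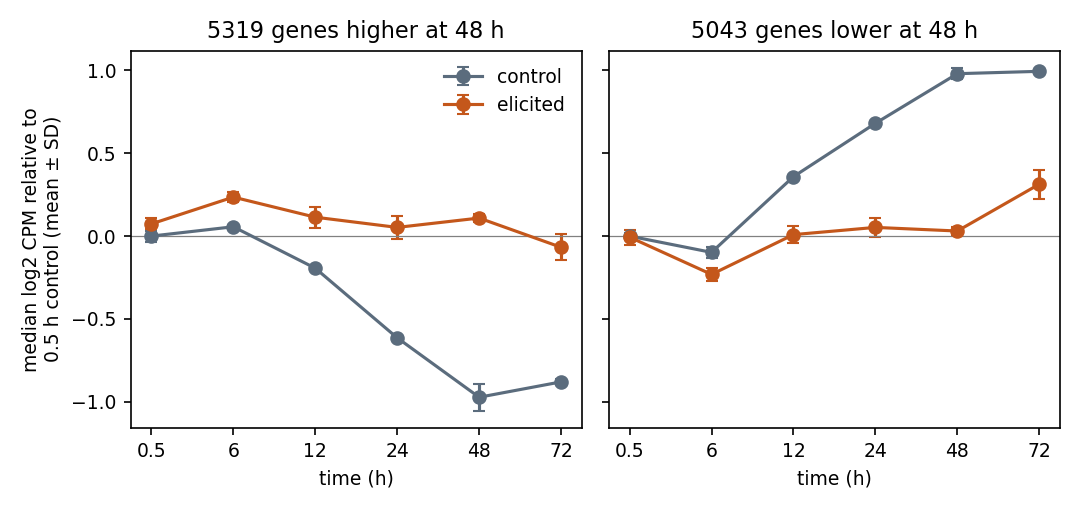
Median log2 CPM, relative to the mean of the 0.5 h controls, of the 5319 genes higher (left) and the 5043 genes lower (right) in elicited cells at 48 h; points are means over libraries and bars are SDs (controls n = 2; elicited n = 3 at 0.5 and 6 h and 4 later). The genes were chosen on the 48 h libraries; at 72 h the controls lie at -0.88 and 0.99 and the elicited cells at -0.07 and 0.31.

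Genes that were higher with elicitation lay next to one another in several places. Runs of 5 or more consecutive annotated genes, each at least 2-fold higher on average and sharing no exon bases with another gene, occurred in 7 regions, and the longest run of lower genes held 3. Adjacent pairs of genes at least 2-fold lower on average were nevertheless more frequent than in shuffled calls, 73 against 33.3 (p = 1e-04, one-sided permutation test with 10000 shuffles), as were pairs of higher genes, 290 against 96.2 (same p and test). The rule of 5 genes was chosen after the values were seen. The longest run held 10 genes on chromosome 8 (3602615 to 3687437), all on the minus strand with 2 or 3 exons, with average log2 fold changes of 1.59 to 3.76. None of the 10 was called at 0.5 or 6 h, 8 were called at 12 h and all 10 at 24, 48 and 72 h (edgeR quasi-likelihood). Their summed level was 2202 ± 596 CPM at 0.5 h, 12280 ± 475 CPM at 12 h, 735 ± 153 CPM at 48 h and 646 ± 102 CPM at 72 h in controls (SD, n = 2 each), and 3599 ± 567 CPM (SD, n = 3), 20011 ± 7460 CPM, 18238 ± 1674 CPM and 12713 ± 1688 CPM (SD, n = 4 each) at those times in elicited cells. The spread at 12 h came from elicited replicate 4, the library that stood apart: it was at 9078 CPM, below both controls (11944 and 12617 CPM), while the other 3 elicited libraries were at 21589 to 25454 CPM. Genes so alike in structure can be near-identical copies, whose reads the counting may have divided between them, so the values of single members are uncertain.

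With a 2nd run nearby, this stretch of chromosome 8 (3602615 to 3962096) held 37 annotated genes, of which 34 were tested. Of these, 23 were at least 2-fold higher on average, all 23 on the minus strand, and 2 were at least 2-fold lower. Genes with 2 exons numbered 23, and 21 of them were among the higher genes. The stretch took 0.317 ± 0.064% of all counts in controls at 0.5 h, 2.14 ± 0.059% at 12 h and 0.312 ± 0.054% at 48 h (SD, n = 2 each). In elicited cells it took 0.456 ± 0.061% at 0.5 h (SD, n = 3), 2.9 ± 1.01% at 12 h and 2.96 ± 0.148% at 48 h (SD, n = 4 each). At 12 h elicited replicate 4 was at 1.42%, below both controls, and the other 3 elicited libraries were at 3.09 to 3.64%. At 72 h controls were at 0.438 ± 0.016% (SD, n = 2) and elicited cells at 2.29 ± 0.311% (SD, n = 4). This share sums genes that moved both ways. The gene with the highest mean level of all genes lay at the start of this stretch (3602615 to 3604828, 2 exons) and took 1.33 ± 0.066% of the counts in elicited cells and 0.0779 ± 0.022% in controls at 48 h. At 12 h the gap was small, with 1.32 ± 0.409% in elicited cells (SD, n = 4) and 1.07 ± 0.001% in controls (SD, n = 2).

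**Figure D5:**
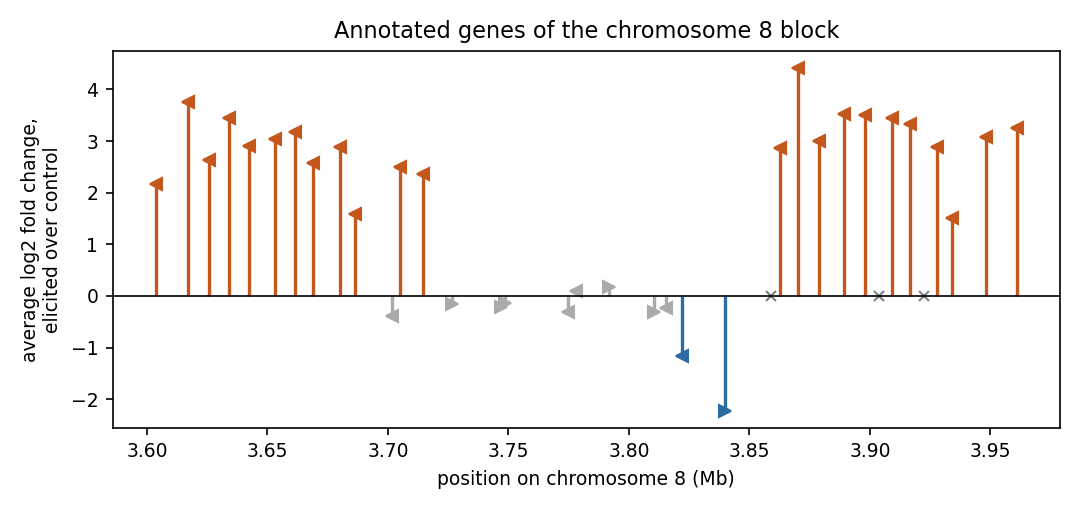
Average log2 fold change of elicited over control cells for the annotated genes at 3602615 to 3962096 on chromosome 8, drawn at each gene's midpoint; triangles point right for the plus strand and left for the minus strand, orange and blue mark genes at least 2-fold higher or lower at an adjusted p below 0.05, grey other tested genes and crosses genes not tested. The 23 higher genes form 2 clusters on the minus strand, with genes that were lower or not changed by 2-fold between the clusters.

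The other 6 regions were chosen by the same rule, which takes in the 48 h libraries, so their higher level in elicited cells at 48 h is not a separate finding. On chromosome 3 (648039 to 694251), 5 genes of 9 to 11 exons on 1 strand had average log2 fold changes of 4.59 to 5.78, and their summed level fell in controls from 29.5 ± 2.58 CPM at 0.5 h to 0.145 ± 0.061 CPM at 72 h (SD, n = 2 each) while elicited cells stood at 34.5 ± 8.64 CPM (SD, n = 3) and 104 ± 27.2 CPM (SD, n = 4). On chromosome 8 (3860972 to 3898727), 5 genes of 1 or 2 exons stood at 419 ± 115 CPM (SD, n = 4) in elicited cells and 4.62 ± 0.357 CPM (SD, n = 2) in controls at 48 h, and as in the longest run the control level was greatest at 12 h, at 283 ± 44.1 CPM (SD, n = 2). On chromosome 9 (4136066 to 4169519), 5 genes had average log2 fold changes of 3.10 to 4.65 and stood at 63.5 ± 19.7 CPM against 1.38 ± 0.383 CPM at 48 h. On chromosome 6 (20804696 to 20849000), 5 genes of up to 13 exons stood at 439 ± 66.5 CPM against 38.5 ± 9.72 CPM at 48 h. A run of 6 genes on chromosome 2 (5294207 to 5388028) stood at 139 ± 22.1 CPM against 10.5 ± 5.96 CPM at 48 h, and another run of 6 on chromosome 3 (19348550 to 19380778) at 81.4 ± 11.1 CPM against 11.3 ± 1.56 CPM. In the last region the elicited level at 0.5 h was 111 ± 32.7 CPM (SD, n = 3) and that of the controls 136 ± 13.9 CPM (SD, n = 2).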

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

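The tests of the library positions (a 6 h library, a 24 h library or a swap) and the tests on overlapping gene models and on read-through among neighbours were chosen only after the result was seen.

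On the second principal component elicited 72 h replicate 1 lay at 44.36, with the other 72 h elicited libraries at 61.53 to 64.93. Elicited 48 h replicate 3 was low in the chromosome 3 region that starts at 19348550, at 64.77 CPM against 86.16 to 88 CPM, and in the chromosome 9 region that starts at 4136066, at 34.06 CPM against 71.37 to 76.2 CPM. Elicited 24 h replicate 4 was low in the chromosome 6 region that starts at 20804696, at 259.9 CPM against 319.8 to 329.1 CPM, and elicited 72 h replicate 1 in the chromosome 8 region that starts at 3860972, at 199.2 CPM against 276.8 to 290.5 CPM. These 5 values far from their group came from 3 libraries and arose in 60 groups of values, in which chance gives about 3. The effect of elicitation differed between times for 9436 genes, and among the named genes for Mal_HE_154X_1_chr004g022320 (adjusted p = 7.82e-08), Mal_HE_154X_1_chr012g011270 (adjusted p = 7.83e-11) and Mal_HE_154X_1_chr010g002150 (adjusted p = 4.96e-09), all by edgeR quasi-likelihood F tests with Benjamini-Hochberg adjustment.

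Elicited 12 h replicate 4 and elicited 48 h replicate 3 lay toward the group of the preceding time. On the axis from the mean 6 h elicited library (0) to the mean 12 h one (1), the first lay at 0.534. This was above the highest 6 h library at 0.224 and below the other 12 h libraries at 0.961 to 1.17, which argues against a 6 h library under a 12 h label. Its deviation had a share of 0.471 in the 6 h direction and of 0.269 in the direction of 12 h controls. The other 12 h libraries had at most 0.167 in the control direction. The bound set in advance was passed by a small margin only, so whether some admixture of control material is part of it is not settled. On the axis from 24 to 48 h, elicited 48 h replicate 3 lay at 0.203, within the 24 h libraries (0.0365 to 0.358) and below the other 48 h libraries (0.962 to 1.18), as a 24 h library under a 48 h label would. A swap with a deposited 24 h library lacks a partner, since the highest 24 h library lay at 0.358. Its lowest chi-square per degree of freedom with a 24 h library was 7.16, where sampling noise gives about 1. This argues against a deposited 24 h library sequenced again. The 24 h libraries differed from each other by 7.99 to 26.1, so another library made from a 24 h flask is not excluded. A slower response in these 2 flasks stays open and was not tested; without both libraries the count of changed genes was 4790 at 12 h and 10269 at 48 h, in place of 4622 and 10362 (edgeR quasi-likelihood).

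Genes at least 2-fold higher on average lay next to each other in 290 pairs without shared exon bases, 3.01 times the 96.2 of shuffled calls (p = 1e-04, one-sided permutation test, the smallest p that 10000 shuffles can give), which argues against overlapping gene models as the whole cause. Pairs unlike in exon number or length were still in excess, 200 against 90.9 and a highest shuffle of 126, a ratio of 2.2. This argues against copies alike in exon number and length as the whole cause. Copies whose gene models differ in exon number count as unlike here and no sequences were compared, so near-identical copies in general stay open. Nested pairs had near-equal counts, so reads appear to have been counted on both strands. A transcript that reads past its end can then add reads to the next gene on either strand. It cannot add reads to a gene whose start faces its own start. Unlike pairs with starts facing were in excess by a ratio of 1.41 (p = 0.04, one-sided permutation test, not adjusted over the kinds of pairs). By a small margin, this argues against read-through from 1 gene of a pair into the other as the whole cause. Read-through from a gene outside the pair across both was not tested. How much of the excess on the same strand (216 against 51.3 pairs) read-through gives was not tested. Pairs alike in structure were 90 against 5.31. In 43.3% of these 90 pairs the fold changes differed by over 2 combined SE, between the bounds set in advance. The combined SE takes the 2 genes of a pair as independent, although both were measured in the same libraries. A joint rise of gene copies and the same reads counted in both therefore cannot be told apart for the alike pairs. Genes at least 2-fold lower were adjacent in 73 pairs against 33.3 in the shuffles, a ratio of 2.19, with 68 against 31.4 for unlike pairs (a ratio of 2.17, highest shuffle 55) and 14 against 6.99 for unlike pairs with starts facing (p = 0.01, one-sided permutation test), so the excess of unlike pairs was not confined to higher genes. Shared control of neighbouring genes and of copies remains a hypothesis found and tested on the same data.

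Among 40 splits of the 34 libraries, with control and elicited labels exchanged within each time and the real split included, 1 gave as many as 12258 genes changed on average, the real one, and the highest other gave 5568. Among 40 splits of the elicited libraries over the times, 1 gave as many as 17075 genes, again the real one, and the highest other gave 9161. With 40 splits no share smaller than 1 of 40 can be reached, so chance assignment of libraries is made less likely but is not excluded. Exchanged labels also mix real groups, which widens the spread within groups and lowers the calls of the other splits.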

How the results depend on the processing

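The alternatives without overlapping gene models, without the 2 libraries that stand apart and with 3 elicited libraries at every time were chosen after the data were seen. Of 1620 alternative values of 68 results, 1430 stayed within fixed bounds and 190 moved. The bounds were 1.5 times for counts and ratios, 0.1 for correlations and the Wilson interval for the single-exon share. For fold changes of the named genes they were an unchanged sign and call. None of these bounds measures the spread between libraries. Most of the results are counts or shares of genes, which cannot change sign. Among the correlations, the ratio of neighbour pairs and the fold changes of the named genes, none reversed. With library size alone the majority of calls turned from higher to lower at each time and on average, as the shares below show. The 4 named genes kept their direction and their calls under each alternative run, on average and at the time of their largest effect (48 or 72 h). Their calls at other times and for dependence on time were not followed over the alternatives. Requiring at least 2-fold lowers every count by construction: 261, 532, 1573, 3344, 5101 and 4394 genes at the 6 times, 2658 on average, 5656 with a time-dependent effect, 10761 over time in controls and 9270 in elicited cells, and 62, 259, 1159, 2856 and 3426 calls shared by consecutive times. For the other alternatives the cause was not tested. At 0.5 h the count was 1517 with DESeq2, 63 with only that time's libraries and 1258 without the 2 libraries that stand apart, and at 6 h 493 with only that time's libraries; calls shared by 0.5 and 6 h were 221 with DESeq2 and 208 without those 2 libraries. With 3 elicited libraries at every time the counts were 1415 at 6 h and 10049 at 48 h, so the rise with time does not rest on the number of libraries. Correlations of consecutive times were 0.109, 0.175, 0.399, 0.599 and 0.68 without a filter, and 0.501 and 0.562 for the first 2 pairs among genes called at either time. Leaving out each library in turn gave 41 to 3010 genes at 0.5 h, 376 to 1360 at 6 h, 1783 to 4575 at 12 h and 5299 to 7692 at 24 h, 20 to 298 calls shared by 0.5 and 6 h, 229 to 749 by 6 and 12 h, 1567 to 3622 by 12 and 24 h, and an r of 0.24 to 0.417 for 6 and 12 h. Library size alone moved the share of higher calls from 58.8% to 22% at 0.5 h, 58.4% to 47.5% at 6 h, 55.8% to 25.2% at 12 h, 54.9% to 31.5% at 24 h, 51.3% to 34.4% at 48 h, 50.5% to 38.9% at 72 h and 50.7% to 30.2% on average. As a replicate block, the title number gave 440 genes at 0.5 h and the description number 1553, and neither moved the totals of genes changed at the later times, on average, over time or with a time-dependent effect by over 1.5 times; libraries with the same title number did not deviate together (median r 0.0135, with 11.1% of pairs over 0.1), and 13 of 34 libraries by title and 9 of 34 by description correlated best with their own number. At this depth and number of libraries 63% of simulated 2-fold changes were recovered at 0.5 h, in counts drawn without deviations of whole libraries.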

Other observations

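The share of single-exon genes was set against matched lists at 0.5, 6 and 48 h, and among genes without shared exon bases, in tests chosen before their results were seen; the matched lists at 12, 24 and 72 h, those on length at times after 0.5 h and those with a library left out were chosen only after the result was seen.

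Genes that were higher within 0.5 h of elicitation were short and simple in structure. Their median exon number was 3 and their median summed exon length 1028 bases. The medians were 7 exons and 2768 bases among genes lower at that time, and 5 exons and 1587.5 bases among genes not called. The higher and the lower genes thus differed in length from genes not called, in opposite directions. At 6 h the median was 4 exons for the higher genes, and at 48 h it was 5 for the higher and for the lower genes. Single-exon genes made up 22.3% of the higher genes at 6 h, 16.6% at 12 h, 15.1% at 24 h and 15% at 72 h, where random lists matched on expression and length averaged 14.4%, 13.1%, 13.2% and 13.3% and each observed share lay above the central 95% of its lists. At 48 h the share was 12.7%, within the central 95% of its lists (12.4 to 13.8%).

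A candidate explanation is that rapidly induced genes in these cells tend to have few introns. This is a hypothesis, and whether a length-dependent difference between libraries gave the pattern was not tested. The excess over length-matched lists was not confined to 0.5 h, however. At 6 h the share was 22.3% against 14.4%, and smaller excesses were seen at 12, 24 and 72 h. The share of 23.4% at 0.5 h lay 10.3 percentage points above the mean of 10000 random lists matched on expression (13.1%, central 95% of lists 10.2 to 16.2%), which argues against expression level as the whole cause. The size of this difference rested on single libraries. It was 5.46, 4.47 and 18.9 points without elicited 0.5 h replicate 1, 2 or 3. Without control 0.5 h replicate 1 or 2 it was 8.82 and 9.18 points, within the central 95% of the random lists. Among genes that share no exon bases the difference was 10.7 points, which argues against overlapping gene models. Matched on length as well, the lists averaged 19% and the difference was 4.38 points (percentile 99.4), past the bound set in advance. That bound took no account of single libraries: beside length-matched lists of its own, the list called without elicited 0.5 h replicate 2 differed by -2.63 points (16.8% of 541 genes against 19.5%) and that without elicited 0.5 h replicate 1 by -0.487 points (17.9% of 1495 genes against 18.4%), while the lists without elicited 0.5 h replicate 3, control 0.5 h replicate 1 and control 0.5 h replicate 2 differed by 15 points (33% of 94 genes against 17.9%), 6.41 points (20.8% of 24 genes against 14.4%) and 6.25 points (23.2% of 69 genes against 16.9%); of these 5 lists only that without elicited 0.5 h replicate 3 lay outside the central 95% of its random lists, so exon number and short length cannot be told apart at 0.5 h. The share was 17.9% with DESeq2, 18.3% and 30.2% with the description or title number as a block, 35.2% with library size alone and 40.8% for changes of at least 2-fold.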
